A study of Arabidopsis thaliana with 3 samples.

How the data were processed

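Binding of HA-tagged AtSDR4L was profiled by ChIP-seq in 2 induced replicates (1 µM β-estradiol) and 1 uninduced control of whole Arabidopsis seedlings, 4 days after imbibition. The series' design text calls the induced samples biological replicates. All 3 ChIPs used the same anti-HA antibody, per the labels' protocols. Libraries were sequenced in paired-end mode on an Illumina instrument and peaks were called with MACS2 2.2.7.1 between treatment and control, per the series' design text. bcl2fastq 2.20, Bowtie2 2.3.5.1, SAMtools 1.7 and the TAIR10 genome are named in the submitters' processing notes. Trimming, mapping quality filters and the treatment of duplicates are not given in the sources used here.

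Each deposited peak list holds positions, a score, a fold enrichment ratio at the summit over the control as the authors' caller gave it, and −log10 p and q values. Every deposited q-value was below 0.1. A peak list shows only regions past that limit and says nothing of regions below it. The version and settings of the IDR program are not given in the sources used here. The authors' deposited table of IDR values follows the standard layout of that program and gives a scaled score and −log10 local and global IDR per matched region. The peaks were called per replicate against 1 shared control, so differences between the induced samples and that 1 library, whatever their origin, enter both lists.

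Peak rows with the same start and end are several summits of 1 peak. They were merged to 1 interval with the summit of the highest q. This gave 9824 peaks from 12865 rows in replicate 1, with 9811 in the nuclear genome, 13 in the mitochondrial and 0 in the plastid genome. It gave 3464 peaks from 4502 rows in replicate 2, with 3423 nuclear, 37 mitochondrial and 4 plastid. Fold enrichments of IDR regions were taken from the peak lists by their q-values, and all regions found a match within 0.001. Read depth is unknown because the files hold no read counts, so no counting error can be given for a fold. Intervals on shares of peaks or genes are exact binomial intervals that treat peaks or genes as independent.

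Peak lists were compared by an overlap of at least 1 bp against 1000 random placements on the same chromosome (200 for overlaps of 50% or more). Reproducible regions were those with a global IDR of at most 0.05. Shares of summits per location were compared with 100000 random positions by an exact binomial test. Gene lists (15 lists, 238 distinct genes, all matched by locus tag) were compared with all other nuclear protein-coding genes by Fisher's exact test with Benjamini-Hochberg adjustment, and 17 classes of gene names formed a second family. The intervals of correlations came from 1000 bootstrap draws of regions. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used. On simulated data with 182 regions and 27432 genes, all planted target genes were recovered. Lists with 2 planted targets among 20 were called in 16% of 50 simulations and lists with 5 in 100%, and 1 of 650 lists without planted targets was called. In these simulations a list of that size with 2 true targets was therefore mostly missed. The number of target genes was not matched to that of the data, where lists of 20 and 18 genes with 2 targets each were called.

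Genes came from a RefSeq gene table of assembly TAIR10.1, which gives gene spans and names but no strand, exons or sequence. Since the files name TAIR10, the table was used only for names and for which genes lie beside or around a summit, and none of its coordinates are printed. The fit of both was checked by shifting the 182 summits: 13.2% lay inside gene spans unshifted, against 49.5% to 63.7% after shifts of 2 to 20 kb in either direction. Promoter, UTR, exon and intron classes were planned and could not be made without strand and exons. Locations were classed by gene spans instead, and the planned target window of 1000 bp upstream to 200 bp downstream of a gene start was applied to both gene ends. This choice was made after seeing the gene table, with several ways of assigning genes looked at side by side, and the window was kept because it is closest to the plan. Name classes were matched on symbols and synonyms (21753 of 27432 coding genes have synonyms) in place of descriptions. A test of sequence motifs at summits, with its alternatives, was planned and not run because no genome sequence was used here.

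Gene lists, thresholds, the tests of the plan and the rule for named genes were fixed before the data were examined, and the target window, location classes and name classes were adapted afterwards as said above. The rule for named genes took the 10 regions with the lowest IDR, up to 4 targets per list by mean fold with more allowed for seed, ABA and gibberellin lists, the AtSDR4L family, and the 5 peaks of highest fold found in 1 replicate only. Alternatives covered the overlap rule, q and IDR thresholds, each replicate alone, and the target window. Sets of all matched regions, regions away from rRNA genes, local random shifts and quintiles by q were added after seeing the data. No peak list of the control was used here, so induced and uninduced samples were compared only through the authors' calls.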

Results

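AtSDR4L is an Arabidopsis transcriptional regulator related to the rice seed dormancy factor SDR4. Its genomic binding was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole seedlings carrying an estradiol-inducible, HA-tagged form of the protein. Seedlings were harvested 4 days after imbibition. The induced group comprised 2 biological replicates grown on 1 µM β-estradiol, and the control was 1 anti-HA ChIP from uninduced seedlings of the same line. Each induced replicate had a list of peaks called by the authors against that single control, and a table matched the peaks of both replicates by irreproducible discovery rate (IDR), which ranks how repeatably a region was found. The peak lists hold no read counts, so the depth behind each library is unknown. Fold enrichment throughout is the authors' value per peak over the uninduced control. The comparison asks which regions were enriched after induction of AtSDR4L-HA, and next to which genes.

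Among the regions found most repeatably, those with the highest fold enrichment lay beside AGL44 and BBX28. AGL44 (ANR1), a MADS-box gene of nitrate-dependent root growth, had a region at chromosome 2: 6017941-6018645 with a fold enrichment of 6.60 in replicate 1 and 4.65 in replicate 2. BBX28, a B-box protein gene of light signalling, had a region at chromosome 4: 13674395-13675351 with 6.45 and 4.50. A region nearest to BRG1 at chromosome 5: 18215518-18216140 had 4.76 and 3.46, and no gene lay close enough to count as its target. These 3 were among the 10 regions with the lowest IDR in the authors' deposited table. Of the other 7, 5 lay within 10 kb of annotated ribosomal RNA genes, on chromosome 2 between 2443 and 10299 and on chromosome 3 between 14196423 and 14201798, and their mean fold over both replicates was only 1.80 to 2.17. The remaining 2 lay at chromosome 3: 13591451-13591792, with folds of 1.73 and 1.59, and chromosome 5: 11185512-11185788, with 2.76 and 2.52. Coordinates are 1-based on TAIR10.

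By mean fold enrichment, a ranking chosen after the values were seen, AGL44 and BBX28 again came first. They were followed by a region beside BRG3, a RING protein gene, at chromosome 3: 4124151-4124731 with 5.01 in replicate 1 and 5.36 in replicate 2. Regions nearest to MAPKKK15 (5.93 and 4.25) and to AP2, a floral homeotic gene (5.38 and 3.32), were also among the 10 with the highest mean.

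**Figure D1:**
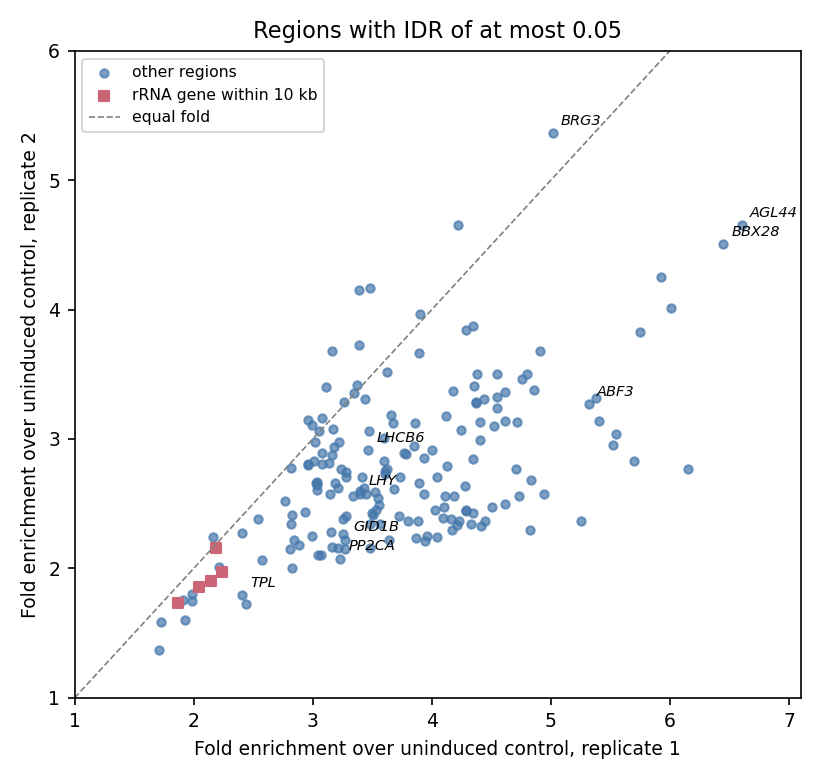
Fold enrichment over the uninduced control in replicate 1 (x axis) and replicate 2 (y axis) for the 182 regions with an IDR of at most 0.05 in the authors' deposited table. Each point is 1 region, squares lie within 10 kb of an rRNA gene, the dashed line marks equal fold, and AGL44 and BBX28 lie at the right end with 6.60 and 6.45 in replicate 1.

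The authors' deposited table held 1784 matched regions, of which 182 had an IDR of at most 0.05 and 66 of at most 0.01. The 182 regions had a median fold of 3.60 in replicate 1 and 2.66 in replicate 2, with a median width of 564 bp. Across all 1784 regions the folds of the replicates had a Spearman correlation of 0.51 (bootstrap 95% interval 0.472 to 0.546). This is a correlation across regions, which are not independent replicates, and both replicates were divided by the same control.

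The replicates differed in how many peaks they gave. Replicate 1 had 9811 nuclear peaks and replicate 2 had 3423. Of the replicate 2 peaks, 1814 (53.0%, exact 95% interval 51.3 to 54.7) overlapped a replicate 1 peak by at least 1 bp, against a mean of 292.6 when they were placed at random on the same chromosome. That is a 6.20-fold excess with a one-sided permutation p of 0.000999, the smallest that 1000 draws can give. In the other direction, 1784 of the replicate 1 peaks (18.2%) were overlapped. Overlap rose with fold enrichment within each list. In replicate 1 it was 9.02% in the lowest quintile and 42.9% (40.7 to 45.1) in the highest, and in replicate 2 it was 32.4% and 69.6% (66.0 to 73.1). Ranked by q-value instead, an order chosen after seeing the data, the highest quintile of replicate 2 was overlapped in only 45.8% (42.1 to 49.7). Part of the overlap may come from the shared control, which cannot be split.

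**Figure D2:**
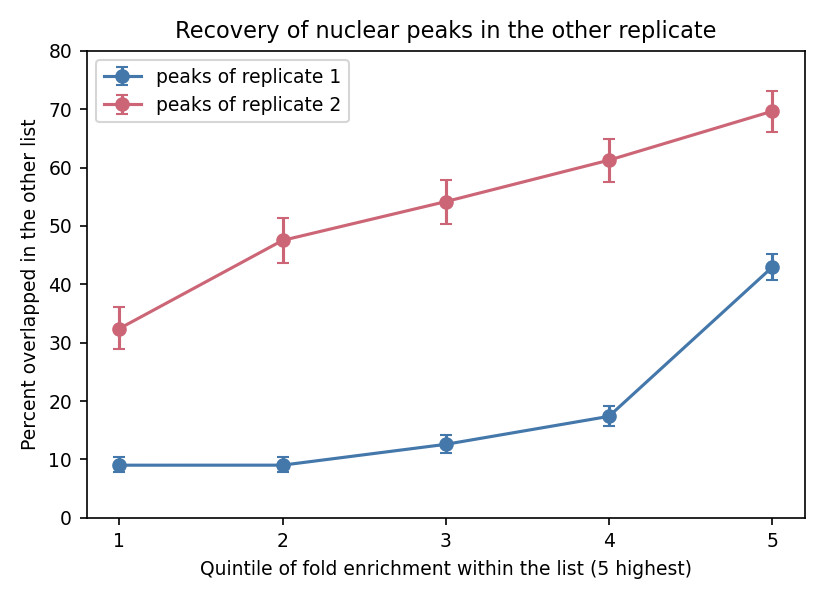
Percent of nuclear peaks overlapped by a peak of the other replicate (y axis, bars are exact 95% intervals) by quintile of fold enrichment within each list (x axis). The share goes from 9.02% to 42.9% for replicate 1 and from 32.4% to 69.6% for replicate 2.

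Reproducible regions lay between genes far more often than random positions did. Of the 182 summits with an IDR of at most 0.05 in the authors' deposited table, 24 (13.2%, exact 95% interval 8.64 to 18.98) fell inside the span of a protein-coding gene, against 54.07% of 100000 random positions (exact binomial test, two-sided p = 1.87e-30). Summits between genes and within 1000 bp of one made up 47.3% (39.8 to 54.8) against 20.6% at random (exact p = 8.7e-16). A further 39.6% (32.4 to 47.1) lay over 1000 bp from any coding gene, against 25.4% (exact p = 2.57e-05). That excess held for reproducible regions and turned into a deficit over all matched regions (18.9%, 17.1 to 20.8, exact p = 9.35e-11) and for the lists of replicate 1 alone (13.4%, 12.8 to 14.1) and replicate 2 alone (11.5%, 10.4 to 12.6). The share inside genes was 38.9% (36.6 to 41.2) over all matched regions. The direction turned for the list of replicate 2 alone, with 56.2% (54.5 to 57.9, exact p = 0.0123) inside gene spans, and did not for replicate 1 alone, with 43.1% (42.2 to 44.1).

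**Figure D3:**
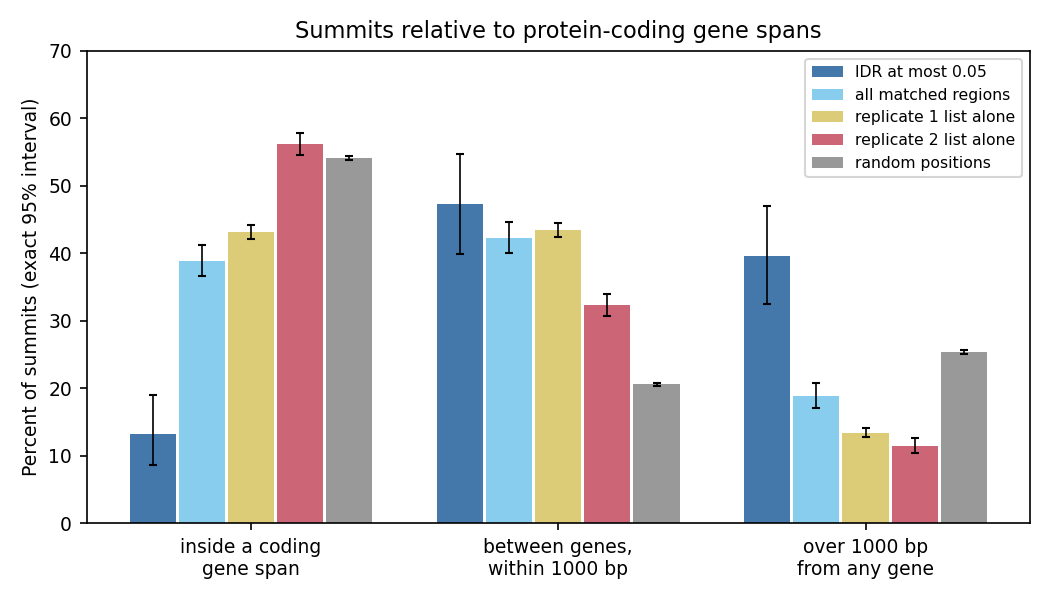
Percent of summits (y axis, bars are exact 95% intervals) inside a coding gene span, between genes within 1000 bp, or over 1000 bp from any coding gene (x axis), for 4 sets of summits and for random positions. Regions with an IDR of at most 0.05 have 13.2% inside gene spans, and the list of replicate 2 alone has 56.2%.

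Among genes next to the 182 regions, abscisic acid (ABA) signalling and photosynthesis genes were over-represented. A gene was counted as a target when a summit lay from 1000 bp outside to 200 bp inside either end of its span, which gave 127 target genes next to 103 of the regions. ABA signalling had 2 targets among 20 genes. They were PP2CA, a protein phosphatase that holds the pathway down, with folds of 3.23 and 2.08, and ABF3, a bZIP activator of ABA-responsive genes, with 5.32 and 3.27. Photosynthesis had 2 among 18, the antenna protein genes LHCB6 (3.46 and 2.91) and LHCA2 (2.44 and 1.73). Both lists had an adjusted p of 0.0287 (Fisher's exact test against all other coding genes, Benjamini-Hochberg over 15 lists), with odds ratios of 24.3 and 27.3. Each call rests on 2 genes, and the region at PP2CA had an IDR of 0.0495, just under the limit. By Fisher's exact test the unadjusted p was 0.00383 for ABA signalling and 0.0031 for photosynthesis. ABA signalling passed the adjustment only because photosynthesis had a lower p. At an IDR of at most 0.01 ABA signalling had 1 target (adjusted p = 0.432) and photosynthesis had 0 (adjusted p = 1) by the same exact test. At an IDR of at most 0.1 photosynthesis had 3 targets (adjusted p = 0.00577) and ABA signalling 2 (adjusted p = 0.0671) by the same exact test. With targets up to 500 bp outside either gene end both lists had 2 targets (adjusted exact p = 0.014). With targets taken from the gene span and 2000 bp around it both lists had 0.0503. In the list of replicate 1 alone, ABA signalling had 17 targets (adjusted exact p = 8.29e-06) and photosynthesis 13 (0.00222), against 31.4% of other genes. In the list of replicate 2 alone they had 7 (adjusted exact p = 0.0149) and 8 (0.0017), against 10.4% of other genes.

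Single targets in the other lists did not pass the test. They were GID1B, a gibberellin receptor gene (3.27 and 2.22), TPL, which encodes the corepressor TOPLESS (2.41 and 1.79), LHY, a morning gene of the circadian clock (3.40 and 2.58), and AP1, a floral identity gene (3.42 and 2.70). Their lists had an adjusted p of 0.274 each by Fisher's exact test. With other rules for targets, the gibberellin list was called with the gene span and 2000 bp around it (3 of 16 genes, adjusted exact p = 0.00401), and the gibberellin and clock lists were called with the nearest gene (2 targets each, adjusted exact p = 0.0298).

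Over all 1784 matched regions, a set chosen after seeing the data and mostly of weak reproducibility, there were 1574 targets. Light signalling and clock genes had 9 targets among 22 (40.9%, exact 95% interval 20.7 to 63.6, against 5.71% of other genes, odds ratio 11.4, adjusted p = 2.26e-05 by Fisher's exact test). CCA1 (3.31 and 1.80) and PRR9 (5.48 and 1.68), which peak in the morning, were among them, and so were GI (1.92 and 3.66) and, singled out after its values were seen, TOC1 (1.70 and 1.76), which peak towards evening. Photosynthesis had 8 among 18 (44.4%, 21.5 to 69.2, odds ratio 13.2, adjusted exact p = 2.26e-05), all of them light-harvesting antenna genes such as LHCA4 (2.60 and 2.49), and none of its 5 Rubisco small subunit and activase genes. That contrast was not tested, and the list of replicate 1 alone had RBCS1A, RBCS2B, RBCS3B and RCA among its targets. ABA signalling had 5 among 20 (25.0%, 8.66 to 49.1, adjusted exact p = 0.0232), adding HAI2, SNRK2.3 and GBF3. In the authors' deposited table the IDR was 0.141 for CCA1, 0.433 for PRR9 and 0.648515, the highest in the table, for TOC1.

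**Figure D4:**
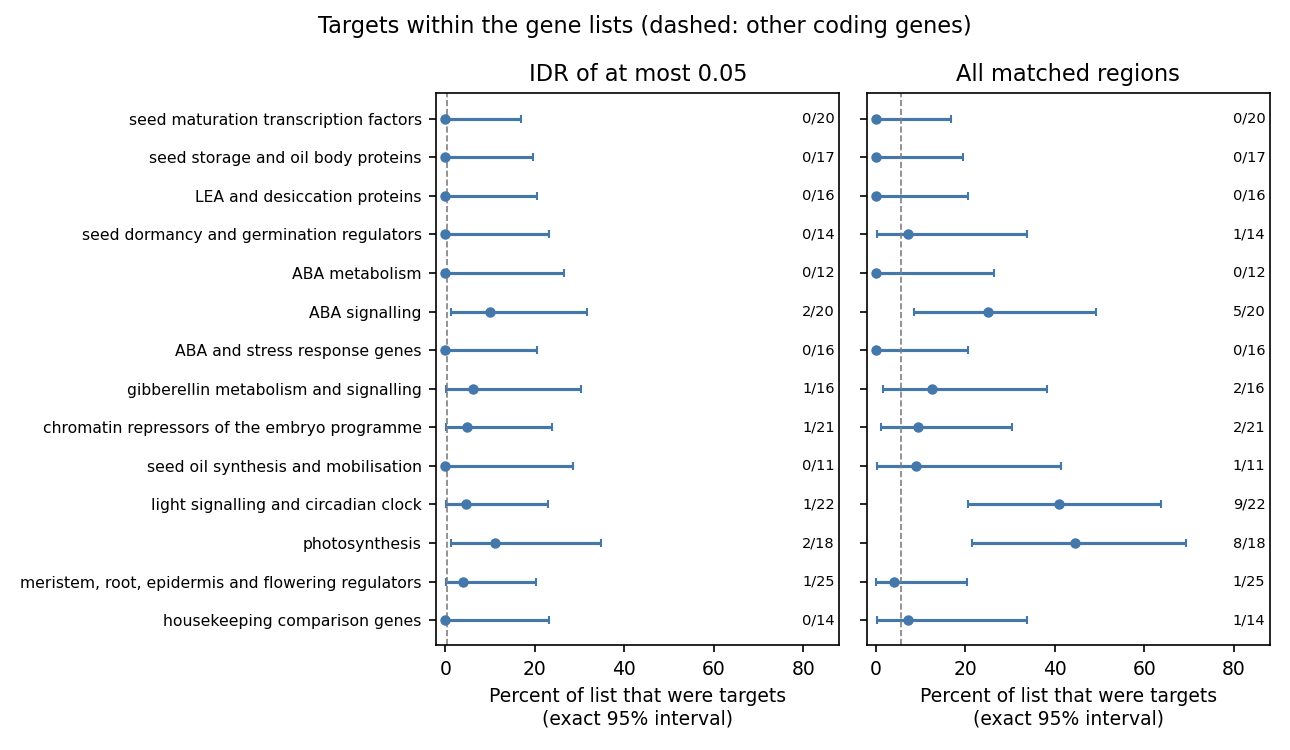
Percent of each gene list counted as targets (x axis, bars are exact 95% intervals) for regions with an IDR of at most 0.05 (left) and all matched regions (right), with targets over members at the right edge and the share of other coding genes dashed. Light signalling and clock genes reach 9 of 22 and photosynthesis 8 of 18 over all matched regions, while the 3 lists of seed maturation, storage and LEA genes have 0.

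Genes of the seed maturation, storage and LEA lists were not among the reproducible targets. These lists were seed maturation transcription factors (20 genes), seed storage and oil body proteins (17) and LEA and desiccation proteins (16). At an IDR of at most 0.05 their 53 genes had 0 targets, which leaves a share of up to 6.72% open (exact 95% interval). Only 0.464% of other genes were targets at that IDR, so 0 among 53 genes does not set these lists apart. The same 53 genes had 0 targets over all matched regions, against 5.75% of other genes (Fisher's exact test, two-sided p = 0.0745), so a lower share was not shown. With each summit given to its nearest gene, 1 of the 53 was a target over all matched regions, against 6.02% of other genes (exact p = 0.376). It was BZIP25, a seed maturation factor, with folds of 2.14 and 1.86 and an IDR of 0.161. By the target window, the list of replicate 1 taken by itself had peaks at 11 of the 53 genes (20.8%, 10.8 to 34.1, against 31.4% of other genes, exact p = 0.104), among them ABI5 (fold 1.95), a bZIP regulator of seed ABA responses, and the 12S globulin gene CRA1 (1.92). The list of replicate 2 had peaks at 2 (3.77%, 0.46 to 12.98, against 10.4%, exact p = 0.171), AGL15 and the LEA gene AT2G21490. AGL15, of the seed maturation factors, also had a peak in the list of replicate 1, but was not a target over all matched regions. By the same target window, seed dormancy and germination regulators, ABA metabolism, ABA and stress response genes, seed oil genes and housekeeping genes also had 0 targets at an IDR of at most 0.05. At that IDR 2 of these lists depended on the window. With the gene span and 2000 bp around it, RGL2 of the dormancy and gibberellin lists was a target (1 of 14 dormancy genes, adjusted exact p = 0.321). With the nearest gene, NCED3 of ABA metabolism was a target (1 of 12, adjusted exact p = 0.213). DAG2, a dormancy regulator of the DOF family, was a target over all matched regions with folds of 1.84 and 2.01.

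The AtSDR4L gene itself, AT3G27250, had a matched region at chromosome 3: 10063571-10063925 with a fold of 2.03 ± 0.243 (SD, n = 2) and an IDR of 0.326 in the authors' deposited table. By the target window, its relative AT5G50360 (DIG2) had a peak in replicate 1, with a fold of 1.79, and not in replicate 2. AT3G48510 (DIG1) had none in either list by that window.

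Gene classes matched by symbol or synonym gave no call at an IDR of at most 0.05. WRKY transcription factors came closest, with ABO3, WRKY47 and WRKY7 among 72 genes (adjusted p = 0.0779 over 17 classes, Fisher's exact test). WRKY genes were called with 5 targets when each summit was given to its nearest gene (adjusted exact p = 0.00139) and with the gene span and 2000 bp around it (adjusted exact p = 0.00498), and for the lists of replicate 1 alone (41 of 72, adjusted exact p = 0.000158) and replicate 2 alone (16 of 72, adjusted exact p = 0.0125). Protein phosphatases 2C and ribosomal protein genes were called for both of these lists too. Receptor-like kinases were called for the list of replicate 2 alone (45 of 150, adjusted exact p = 4.94e-10). They were not called for replicate 1 alone (57 of 150, adjusted exact p = 0.317). Over all matched regions, the set chosen after seeing the data, protein phosphatases 2C (5 of 18, adjusted exact p = 0.024) and receptor-like kinases (19 of 150, adjusted exact p = 0.0191) were called, and WRKY genes were not (9 of 72, adjusted exact p = 0.123) unless each summit was given to its nearest gene (11 of 72, adjusted exact p = 0.0155). That nearest-gene rule also added calls for bZIP (10 of 49, adjusted exact p = 0.00483) and zinc finger genes (11 of 69, adjusted exact p = 0.0147).

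Among peaks found in replicate 1 only, the 5 with the highest fold ran from 4.57 to 5.66. The first lay beside AT4G39790 at chromosome 4: 18461570-18462216, and the other 4 were nearest to AT1G32660, RHA1A, AT2G43500 and AT1G57550. Among those found in replicate 2 only, the 5 ran from 3.82 to 5.60. They included peaks at chromosome 5: 21509733-21512776 nearest to AT5G53050, at chromosome 1: 232277-234523 beside AT1G01640 and SPPL4, and at chromosome 5: 8516237-8516828 beside BZIP9. The peak at chromosome 1: 29455134-29457789 had AT1G78280 as its target by the window and SNRK2-8 as its nearest gene. The peak at chromosome 3: 296055-297843 had AT3G01820 and LYK2, a LysM receptor kinase gene, as targets by the window and AT3G01830 as its nearest gene. Of the 1609 nuclear peaks found in replicate 2 only, 74.3% (exact 95% interval 72.1 to 76.5) had their summit inside a gene span, against 40.1% (37.9 to 42.4) of those shared with replicate 1.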

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

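Signal outside the nuclear genome was singled out because peaks were called there above the uninduced control. Replicate 1 had 13 mitochondrial peaks with a median fold of 1.25 and a highest fold of 1.72. Replicate 2 had 37 mitochondrial peaks with a median of 1.26 and a highest fold of 2.05, and 4 plastid peaks with a highest fold of 1.12. Of the 37, 8 were overlapped in replicate 1. The lowest IDR of a mitochondrial region in the authors' deposited table was 0.358, so 0 of them passed 0.05. No explanation was tested for them.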

How the results depend on the processing

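Alternatives not planned before the data were examined were the set of all matched regions, regions away from rRNA genes, local shifts and quintiles by q. Overlap of the replicates stayed above random placement under every rule run, with 1086 peaks at a reciprocal overlap of 50% (72.6 at random), and 906 and 449 peaks with −log10 q of at least 5 and 10 in both lists. With local shifts the random mean was 368.3 in place of 292.6. The Pearson correlation of log2 fold was 0.55. At an IDR of at most 0.01 the authors' deposited table gave 66 regions, 40 targets and 0 called lists, with 1 ABA signalling target (adjusted p = 0.432) and 0 photosynthesis targets (p = 1), fewer regions being tested. At an IDR of at most 0.1 it gave 301 regions, 221 targets and 1 called list, photosynthesis (3 targets, adjusted exact p = 0.00577), while ABA signalling had 2 targets at an adjusted exact p of 0.0671. All 1784 regions gave 1574 targets, 9 of them in the clock list. Using 1 replicate's list alone, the share of summits inside gene spans was 43.1% without replicate 2, still below random positions. It was 56.2% without replicate 1, which reversed the direction. Targets ranged from 2853 to 8614, and clock list targets from 9 to 19, past the threshold in both. ABA signalling and photosynthesis were past the threshold in both as well. With gene spans and 2000 bp around them there were 221 targets and 1 called list, gibberellin metabolism and signalling (3 targets, adjusted exact p = 0.00401), and ABA signalling and photosynthesis had 2 targets each at an adjusted p of 0.0503. With the nearest gene, 4 lists were called, the clock list with 2 targets. The cause of these changes was not tested. Leaving out the 5 regions near rRNA genes left 124 targets and 2 called lists. No paired analysis was possible because the control has 1 library. Motif alternatives were not run. Without read counts the depth of each library, and so how much the shorter list of replicate 2 reflects depth, stays unknown.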

Other observations

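The gene families described first, from the photosystem subunits to the TOPLESS genes, and the scan of symbol stems were chosen after such genes were seen among the targets and some 17 families had been looked at informally, so their p-values are descriptive. Genes of the photosystem subunits, picked from 4 targets at an IDR of at most 0.05 in the authors' deposited table (PSAN, PSBQA, PSBX and PSI-P), had 19 targets among 25 over all matched regions (76.0%, exact 95% interval 54.9 to 90.6, against 5.67% of other genes). Of the other 21 subunit genes, 15 were targets. These counts depend on the target window: 3 of the 4 regions had another gene nearest (all but PSBQA), and with each summit given to its nearest gene 1 subunit gene was a target at an IDR of at most 0.05 in that table and 10 of 25 over all matched regions (40.0%, 21.1 to 61.3, against 5.98% of other genes). Their enrichment was mostly modest, with folds of 2.35 and 1.98 at PSAG and 1.40 and 1.57 at PSBO2, and reached 3.08 and 2.89 at PSI-P. GPRI1 (GLK1), an activator of chloroplast genes, had a region with folds of 3.60 and 3.01. Of the 4 LNK genes, light-linked components of the clock, 3 were targets at an IDR of at most 0.05 in that table. They were AT5G64170 (LNK1), with folds of 3.80 and 2.37, AT3G54500 (LNK2), with 4.23 and 2.37, and AT3G12320 (LNK3), with 3.86 and 3.12. The remaining LNK gene, AT5G06980, was a target at that IDR when each summit was given to its nearest gene.

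B-box genes of light signalling had 4 targets among 30 at an IDR of at most 0.05 in the authors' deposited table (BBX28, BBX29, BBX15 and COL9) and 11 over all matched regions. Among 422 groups of genes sharing a symbol stem, BBX was the only one called at that IDR (adjusted p = 0.044, Fisher's exact test, 3 of 20 genes whose main symbol starts with BBX). That call was absent over all matched regions (6 of 20, adjusted exact p = 0.0959), where the stems LHCA (5 of 6, adjusted exact p = 0.00149) and SPL (6 of 16, adjusted exact p = 0.0362) were called, and absent without replicate 1 (adjusted p = 0.209) and without replicate 2 (adjusted p = 0.117). The SPL call counted SPL10 and SPL11 as separate targets although both came from 1 region, with an IDR of 0.648515. SPL5 had that same IDR. TOPLESS corepressor genes had 3 of 5, TPL (2.41 and 1.79), TPR1 (2.17 and 2.24) and TPR3 (2.57 and 2.07). With each summit given to its nearest gene, NCED3, which makes the rate-limiting enzyme of ABA synthesis, had a region with folds of 4.37 and 3.29, and GA20OX3 of gibberellin synthesis had 3.89 and 3.67.

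For clock, photosynthesis and ABA signalling genes among the matched regions, the choice of these 3 lists and the housekeeping tests came after the result was seen. In 10000 gene sets matched on flank length the mean was 1.37 targets (upper end of the central 95% of sets 4) against 9 for the clock list. It was 0.934 (3) against 8 for photosynthesis and 1.26 (4) against 5 for ABA signalling. Median flanks were 1038.5 bp for the clock list and 1108 bp for photosynthesis, against 1134 bp for all genes, so theirs were not longer. Those of ABA signalling were longer (1311 bp), and its matched sets reached up to 6 targets. These values argue against longer intergenic flanks, for ABA signalling by a narrow margin. The counts also argue against equal recovery of any transcribed gene. Of 81 housekeeping and ribosomal protein genes 8 were targets, where 5.74% of all coding genes were. The exact p for the difference was 0.00161 for the clock list and 0.00141 for photosynthesis. It was 4.4e-08 for the 21 photosystem subunit genes left after taking out the 4 that prompted the list (1.9e-05 with the nearest gene, 9 of 21 against 3 of 81). For ABA signalling (exact p = 0.127) this cannot be told apart with 20 genes. Ribosomal protein genes were not called over all matched regions (7 of 67, adjusted exact p = 0.331). They were called for the lists of replicate 2 alone (16 of 67, adjusted exact p = 0.0101) and replicate 1 alone (31 of 67, adjusted exact p = 0.0499). Recovery that grows with very high transcription stays open, because expression was not measured here; summits lay inside a gene span for 13 of the 20 regions at photosystem genes, and for 2 of 9 at clock, 3 of 9 at photosynthesis and 1 of 7 at ABA signalling genes. A difference in harvest time or light between induced and control seedlings could also act on these genes, and neither it nor binding by AtSDR4L, the biological hypothesis, was tested.

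Regions next to rRNA genes took 5 of the 10 lowest IDR values in the authors' deposited table, and the test of their fold took its present form after the result was seen. Their mean fold was 2.01, against a median of 3.22 for the 177 other regions with an IDR of at most 0.05, and their mean −log10 q in replicate 1 was 319 against a median of 48.3. Such q-values at modest fold would come with read pileup, but the regions had been picked by an IDR taken as ranked on q. The region at chromosome 3: 13591451-13591792, with no rRNA gene within 10 kb, had a mean fold of 1.66 and was also among the 10, so fold does not single out the regions at rRNA genes. It had 3 coding genes within 100 kb, and the region at chromosome 5: 11185512-11185788 had 7. AGL44, BRG1 and BBX28 had 22, 40 and 59, and the regions next to rRNA genes had 3 to 19. Whether those 2 gene-poor regions also hold sequence present in many copies was not tested. Whether read pileup over sequence present in many copies gave the regions at rRNA genes their rank cannot be told apart from other sources without read counts, and no biological explanation was tested.

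Peaks found in replicate 2 only lay inside gene spans more often than shared peaks, and the tests here against random positions and on replicate 1 for response genes were written after the results they concern had been seen. For replicate 2 the excess held within quintiles of fold (Cochran-Mantel-Haenszel odds ratio 3.65, 95% interval 3.14 to 4.24), against lower fold as its source, and the share of 74.3% exceeded the 54.07% of random positions, against scattered chance calls alone. For replicate 1 the crude excess (44.8% against 35.8%) turned within quintiles (odds ratio 0.856, 0.760 to 0.964), so no excess was left among peaks of like fold. That odds ratio met neither prediction on fold as written, and 44.8% lay below random positions, against chance calls alone. A candidate explanation for replicate 2 is strong transcription of rapidly induced touch, wound and immune genes: of 24 such genes, listed after others like them had been seen in that replicate and leaving those out, 7 (29.2%, exact 95% interval 12.6 to 51.1) held a summit of a replicate 2 only peak, against 3.94% of other genes (Fisher's exact test, two-sided p = 2.9e-05) and a mean of 0.885 genes in sets of the same gene length. The 7 were CML37, CML38, JAZ1, JAZ8, BAP1, ATL6 and EXO70B2. These genes leave most of the 1196 replicate 2 only summits inside gene spans unexplained, and transcription was not measured here. The share for replicate 1 only peaks was 8.33% (1.03 to 27.0) against 12.3%, too few genes to decide. No biological explanation by AtSDR4L binding or a difference between groups was tested because the replicates form 1 group.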
